A study of Homo sapiens with 8 samples.

How the data were processed

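RNA from 8 samples of cultured cells was measured on 1-colour Agilent human arrays: Ishikawa cells transfected with ERα cDNA and given E2 (1e-07 M) or ethanol for 24, 48 or 72 h (1 array for each of the 6 combinations), and 1 array each of untreated Ishikawa and untreated HEC-50B. Per the labels' protocols, treated cells were moved to phenol-red-free medium with charcoal-treated serum, total RNA was taken with a column kit, and Cy3-labelled cRNA was hybridised. Whether the untreated cells saw the same medium is not stated there. All 8 arrays lay on 1 slide and came from 1 scan per the file headers. In slide row 1 stood untreated Ishikawa and the 3 E2 arrays, in row 2 the 3 EtOH arrays and HEC-50B.

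Per the file headers, the authors' scanner images were read with Agilent Feature Extraction 11.0.1.1, which gave background-subtracted processed signal intensity, raw median intensity of spot and background, and flags. The deposited series table holds the same processed signal intensity on a linear scale, neither scaled between arrays nor centred: it equalled the scanner files within a relative 1e-06 for all 57901 single-spot probes on each array, and the spot mean for the 300 probes with several spots. Its column medians were 14.5 for untreated Ishikawa, 12.2, 12.4 and 14.2 for E2 at 24, 48 and 72 h, 10.1, 15.9 and 14.2 for EtOH, and 9.05 for HEC-50B. Quality flags (well above background, non-uniform, population outlier), deposited as other values of 0 or 1, were used as filters.

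From the deposited signal intensity, log2 values were computed per spot, 2075 control spots and spots with an outlier flag were left out, and spots of a probe were averaged. Before flagged spots were left out and spots were averaged, each array's 75th percentile over all its non-control spots was subtracted. Of 58201 probes, 31104 were named with 1 gene (22439 genes) by matching their RefSeq accession to a table of assembly GRCh38.p14, which was used for names only; the other 27097 kept their probe ID. The headers name build hg19, and no coordinates are given because the builds differ. A probe entered a fit if it was well above background on at least 3 of the fit's arrays and had a usable spot on all of them. The probe with the highest mean level over the 8 arrays stood for its gene, and other probes of a named gene that went the other way are mentioned.

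Models were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 2-sided, Benjamini-Hochberg over genes, adjusted p under 0.05). E2 against EtOH used the 6 treated arrays with time as a factor (2 residual degrees of freedom, 3.33 from the prior), since the arrays are matched by collection time in the labels. The change of the effect with time used treatment, hours and their product (2 residual degrees of freedom). The time trend used hours and treatment (3 residual degrees of freedom), and slopes are given per 24 h. Each arm against untreated Ishikawa used all 7 Ishikawa arrays with the 3 times as spread (4 residual degrees of freedom); the lone untreated array was taken to vary like the others. HEC-50B was compared without a test, as genes at least 4-fold apart and well above background on at least 1 of the 2 arrays. Gene lists with at least 5 tested genes were tested with camera (preset correlation 0.01, then an estimated one) and fry; 28 lists were written before the data were examined, and 702 of their 716 entries were on the array.

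The genes named were also fixed before the data were examined: for E2 against EtOH the largest calls each way, or where fewer passed, genes at least 2-fold apart the same way in all 3 pairs; for the other fits the 8 largest rises and falls past the threshold; up to 4 members of each list with the largest change; members of the 2 estrogen-target lists past the threshold; and for HEC-50B the 10 largest differences each way outside the Ishikawa range. ESR1 was read as the transfected gene. PGR and GREB1 in E2 against EtOH, GREB1 against untreated cells, the list members named for HEC-50B and the motile-cilium examples fall outside this rule and were chosen after their values were seen. Some genes that the rule selects are not reported here.

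For probes with replicate spots, the root mean square difference between same-time E2 and EtOH arrays was set against the standard error of the spot means. It was 6.75, 4.82 and 9.62 times that error at 24, 48 and 72 h, so no array was read as a copy of another. A second hybridisation of the same RNA could also exceed that error. Each fit was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale, drawn with variances from the fitted prior. The signal floor, the lowest normalised log2 value well above background, ran from −4.50 (untreated Ishikawa) to −3.68 (HEC-50B). Alternatives were background correction by normexp with offset 50 and quantile normalisation, quantile and median scaling, other filters on dim probes, the mean of a gene's probes, a trend in the prior, the deposited table, each array or pair left out, other time terms and thresholds, and some chosen after the data were seen. Normexp used the spot median, because the files hold no mean column.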

Results

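RNA levels were measured on 8 one-colour Agilent arrays, each with 60901 non-control spots. Ishikawa, a human endometrial adenocarcinoma line, was transfected with estrogen receptor alpha (ERα) cDNA and 24 h later given 17β-estradiol (E2, 1e-07 M) or its solvent ethanol (EtOH). Each treatment had 1 array at 24, 48 and 72 h. Untreated Ishikawa and untreated HEC-50B, another human endometrial cancer line, had 1 array each. No time point had replicates, and the labels do not say whether the times came from separate cultures. Between 45.8% (HEC-50B) and 50.5% (E2 at 72 h and untreated Ishikawa) of the spots on an array lay well above background. The 75th percentile of the deposited signal was 335 for untreated Ishikawa, 242, 261 and 250 for E2 at 24, 48 and 72 h, 182, 351 and 279 for EtOH, and 198 for HEC-50B. The number of arrays limits the precision of every comparison. All levels are log2 signal minus the array's 75th percentile. A fold against a group in which no array lay well above background is a lower bound, written "at least": that group's level was set to the lowest normalised signal well above background on its arrays, or to its own level where that was higher.

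ESR1, which encodes ERα and was the transfected gene, was read first as a check of the labels. On its brightest probe (A_33_P3379356) the level was 4.20 in untreated Ishikawa. It was 2.88, 1.98 and 0.96 with E2 at 24, 48 and 72 h, and 2.98, 2.25 and 0.73 with EtOH. The mean of the 6 transfected arrays minus untreated was −2.23 (SD of the 6 arrays 0.94). On probe A_24_P383478 that difference was −0.77 (SD 0.91), and on A_23_P309739 it was 0.23 (SD 0.52). The mean over the 6 transfected arrays was thus above untreated on 1 of the 3 probes. On that probe the level was −0.84 in untreated cells, −1.15 at 24 h in both arms, and −0.09 with E2 and 0.08 with EtOH at 72 h. The files do not place the probes within the transcript. A probe outside the transfected cDNA would not report it, so these levels do not settle the labels. HEC-50B was above background on probe A_24_P383478 (−0.89) and not on the other 2.

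**Figure D1:**
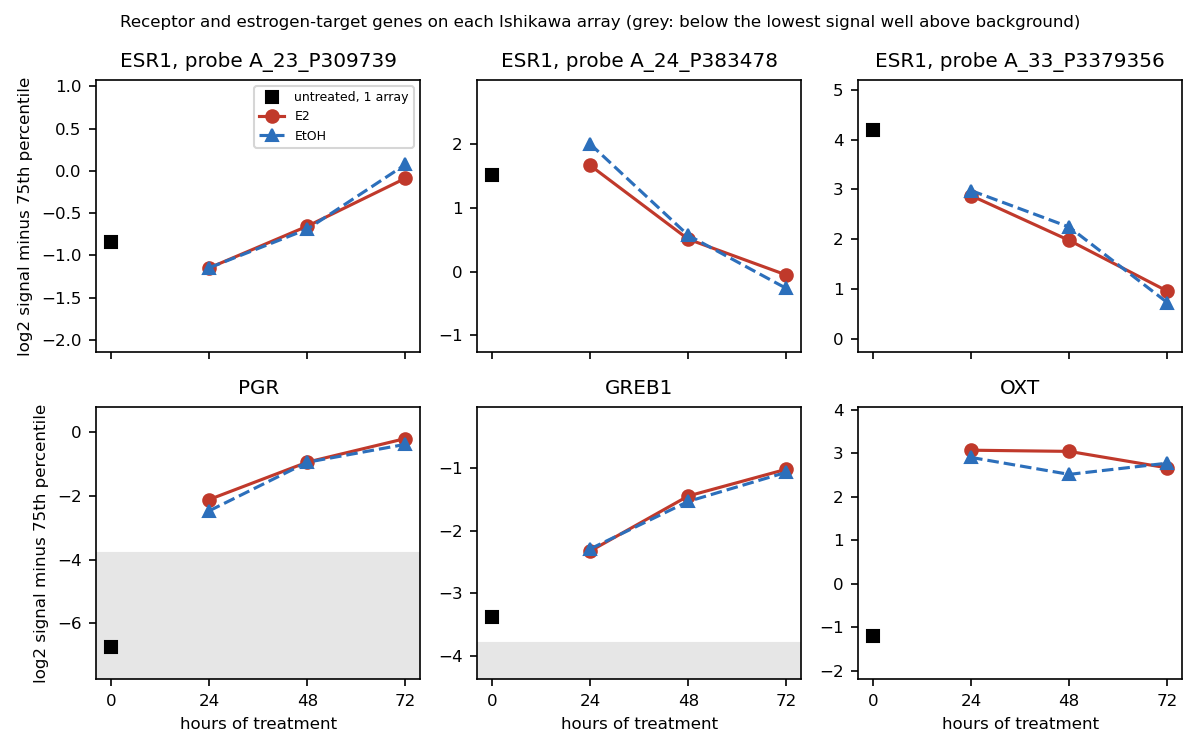
Levels (log2 signal minus the array's 75th percentile) of 3 ESR1 probes, PGR, GREB1 and OXT against hours of treatment on the 7 Ishikawa arrays, 1 point per array. OXT was −1.19 in untreated cells and 3.07, 3.04 and 2.66 with E2, against 2.90, 2.51 and 2.77 with EtOH.

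E2 against EtOH asked which genes respond to estradiol in ERα-transfected Ishikawa cells. PGR, the progesterone receptor and a classical estrogen target, differed by 0.18 (SE 0.11) over the 3 time-matched pairs on its brighter probe and by −0.14 on the other, and GREB1, another such target, by 0.03 (SE 0.09). Of 60 tested genes of the 2 estrogen-target lists, 54 were above background on all 6 arrays, and among these the fitted difference ran from −0.46 (SE 0.18) for CTSD, the lysosomal protease cathepsin D, to 0.33 (SE 0.20) for EGR3, an immediate early transcription factor. OLFM1, a secreted olfactomedin-family glycoprotein, was not above background at 24 h and stood at 0.36 and 0.44 in the 48 and 72 h pairs. KRT13, an epithelial keratin, was not above background at 72 h and stood at −0.34 and −0.51 in the 24 and 48 h pairs. None of these passed the test: limma's adjusted p was 0.728 for CTSD, OLFM1 and KRT13, and 0.743 for EGR3 and PGR.

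Over all 22183 genes tested, limma called 0 at an adjusted p under 0.05, with 1502 at an unadjusted p under 0.05 where 1109 would come by chance. The smallest adjusted p was 0.404. Of the 60 estrogen-list genes, 58 had the upper 95% bound of E2 minus EtOH below 1 on the log2 scale, that is below a 2-fold rise, as had 53 of the 54 above background on all 6 arrays. Of the 60, 10 were higher and 7 lower with E2 in all 3 pairs, where chance gives 12.5% each way. No gene was at least 2-fold higher with E2 in all 3 pairs, and 2 had values at least 2-fold lower, of which 1 had a name. That was PLLP, plasmolipin, a membrane proteolipid, which did not pass (limma adjusted p 0.404). All 3 of its E2 levels lay below background, so the size of its difference was not measured. At single times, without replicates, 120 genes were at least 2-fold higher and 270 lower with E2 at 24 h, 152 and 72 at 48 h, and 181 and 89 at 72 h. In simulated data with this spread and independent noise, 100 genes were changed by 1 and 100 by 2 on the log2 scale together. The fit recovered 68% and 95% of them. With fewer changed genes the Benjamini-Hochberg cutoff is stricter, so these shares do not hold for a response of few genes. PLLP, with an unadjusted limma p of 1.8e-05, did not pass. Leaving out the 48 h pair left 1 residual degree of freedom and gave 91 calls (31 higher, 60 lower). Scaling each array to its median gave 8 (2 higher, 6 lower). That median lies near the background limit, since 47.95% (EtOH at 24 h) to 50.51% (E2 at 72 h) of spots on the treated arrays were well above background. Treatment also coincided with the slide row for all 6 arrays, so the 2 cannot be separated.

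**Figure D2:**
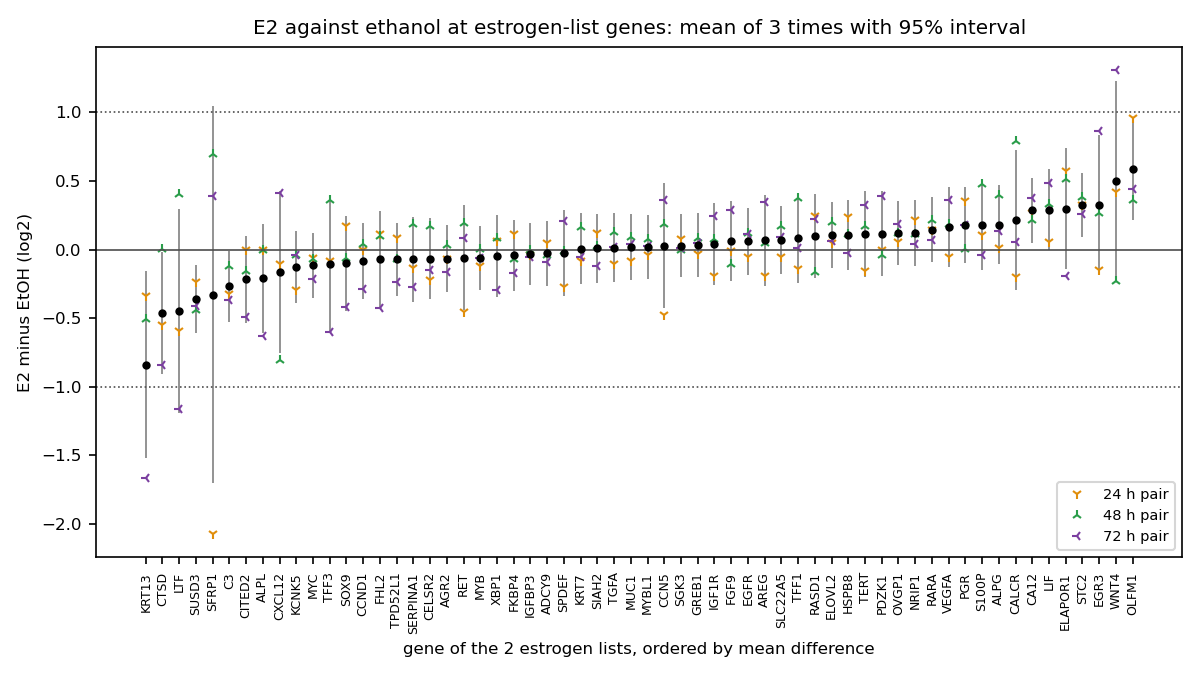
E2 minus EtOH (log2) for each tested gene of the 2 estrogen-target lists, with the mean of 3 pairs (black), its 95% interval from limma (line) and the 24, 48 and 72 h pairs (coloured marks); dotted lines mark 2-fold. Pairs below background are included, and the upper bound lies below 1 for 58 of 60 genes.

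Of 28 gene lists fixed before the data were examined, 4 were lower with E2 than with EtOH by limma's camera with its preset correlation of 0.01. Respiratory chain and ATP synthase subunits had a median of −0.16, with 3 of 28 genes above 0 (adjusted p 8.0e-06, and adjusted p = 0.993 with an estimated correlation). ATP5F1B and ATP5F1A, subunits of the mitochondrial ATP synthase, stood at −0.63 (SE 0.17) and −0.40 (SE 0.12), and SDHB of complex II at −0.40 (SE 0.13). Mitosis genes had a median of −0.08, with 1 of 29 above 0 (adjusted p 0.00306, and adjusted p = 0.993 with an estimated correlation). Among them the mitotic kinase AURKA was at −0.31 (SE 0.11) and CDC20, an activator of the anaphase-promoting complex, at −0.28 (SE 0.12). Ribosomal protein genes had a median of −0.08, with 4 of 30 above 0 (adjusted p 0.00306, and adjusted p = 0.993 with an estimated correlation), RPS3 standing at −0.36 (SE 0.13) and RPL7 at −0.29 (SE 0.10). Sterol synthesis genes had a median of −0.09, with 4 of 25 above 0 (adjusted p 0.00937, and adjusted p = 0.993 with an estimated correlation), among them the sterol oxidase MSMO1 at −0.28 (SE 0.15) and the squalene synthase FDFT1 at −0.27 (SE 0.11). In these 4 lists 0 genes passed limma over all genes tested and 0 adjusted over the list alone. The medians of the 2 estrogen-target lists were 0.02 and 0.03 (adjusted p 0.790 and 0.632). Median scaling, which shifted the median of all genes by −0.04, took these medians below 0 while the direction camera gave stayed up. The 4 medians above stayed negative under all 5 scalings, but the mitosis call was lost under quantile normalisation (adjusted p 0.0605) and the sterol call under quantile normalisation and median scaling (0.157 and 0.0564). Leaving out the 72 h pair left 1 list call while leaving out the 24 h pair gave 7.

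**Figure D3:**
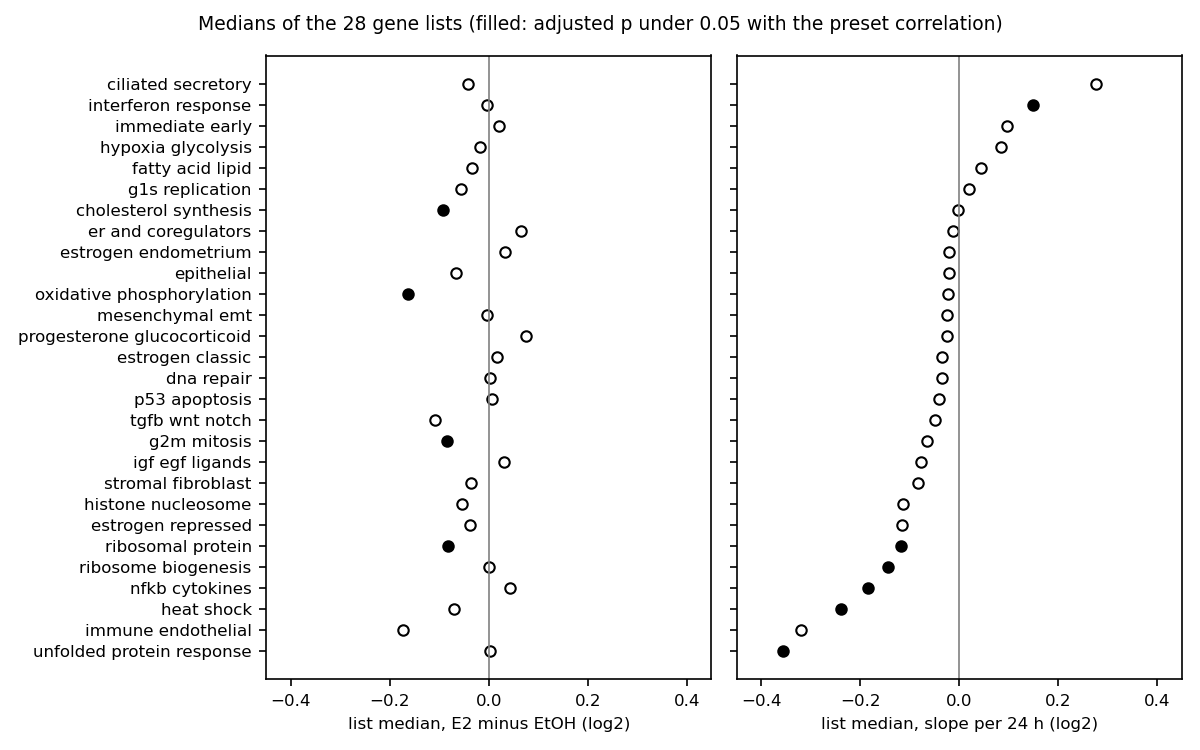
Median of each of the 28 gene lists for E2 minus EtOH (left, log2) and for the slope per 24 h (right, log2); filled points had a camera adjusted p under 0.05 with the preset correlation, which 0 of them kept with an estimated one. The median of the unfolded protein response list was −0.36 per 24 h.

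Whether the E2 effect itself grew or shrank with time was asked with a treatment-by-time term. The difference between E2 and EtOH changed with time for 0 of 22183 genes in limma, with 244 at an unadjusted p under 0.05 (smallest adjusted p 1.00). Simulated changes of 1 and 2 on the log2 scale were recovered for 0% of genes, so changes of that size were not detectable with these arrays. Leaving out the E2 array at 24, 48 or 72 h left 1 residual degree of freedom and gave 55, 81 and 151 calls.

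Time after treatment, common to both arms, was followed over 24, 48 and 72 h. PGR rose by 1.00 per 24 h on the log2 scale (SE 0.12, limma adjusted p 0.0164, 6 arrays), from −2.11 at 24 h to −0.20 at 72 h with E2 and from −2.47 to −0.38 with EtOH. OLFM1 rose at least 6.51-fold from 24 to 72 h, ALPG, a germ-cell type alkaline phosphatase, 4.17-fold (slope 1.03, SE 0.10) and GREB1 2.41-fold (slope 0.63, SE 0.09). ESR1 fell by 1.04 per 24 h on its brightest probe (SE 0.10, adjusted p 0.0135), with 1 of 2 other probes going the other way. AREG, the epidermal growth factor receptor ligand amphiregulin, fell by 0.84 per 24 h (SE 0.09) and the small heat shock protein HSPB8 by 0.99 (SE 0.12), and the secreted ligand WNT4 fell at least 2.69-fold from 24 to 72 h. Of 38 genes in the list of classical estrogen targets, 4 rose and 2 fell over all genes tested, and 7 rose and 4 fell adjusted over the list alone. For 25 endometrial estrogen targets the counts were 3 and 1, and 4 and 1 adjusted over the list alone. Neither list passed camera (adjusted p 0.722 and 0.664).

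Among the 8 largest fitted slopes over time, CFAP100, a cilia- and flagella-associated protein, rose at least 6.0-fold from 24 to 72 h, the axonemal protein gene CFAP276 at least 7.86-fold, CLXN, calaxin, at least 3.12-fold and ODAD1, which docks outer dynein arms, 11.8-fold (slope 1.78, SE 0.17). CAMP, the antimicrobial peptide cathelicidin, rose at least 4.78-fold, COXFA4L2 at least 6.82-fold, ASCL2, a basic helix-loop-helix transcription factor, 9.67-fold (slope 1.64, SE 0.18), and the endocytic receptor gene LY75 at least 3.51-fold. Large falls were those of ARHGAP25 (at least 2.32-fold), TAC1, the substance P precursor (at least 4.64-fold), ANKRD1, a target of YAP (slope −1.38, 6.80-fold), MAMDC2 (at least 5.0-fold), CST6 (−1.27, 5.81-fold), the orphan nuclear receptor NR4A3 (−1.26, 5.73-fold) and RAB39B (−1.25, 5.66-fold). Of 14 markers of ciliated and secretory endometrial epithelium, 4 rose and 1 fell over all genes tested, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p 0.0893). FOXJ1, the master transcription factor of motile cilia, rose by 1.39 per 24 h (SE 0.08) and TPPP3, a tubulin-binding protein, at least 4.11-fold from 24 to 72 h, while the chemokine gene CXCL14 fell by 0.99 (SE 0.10).

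**Figure D4:**
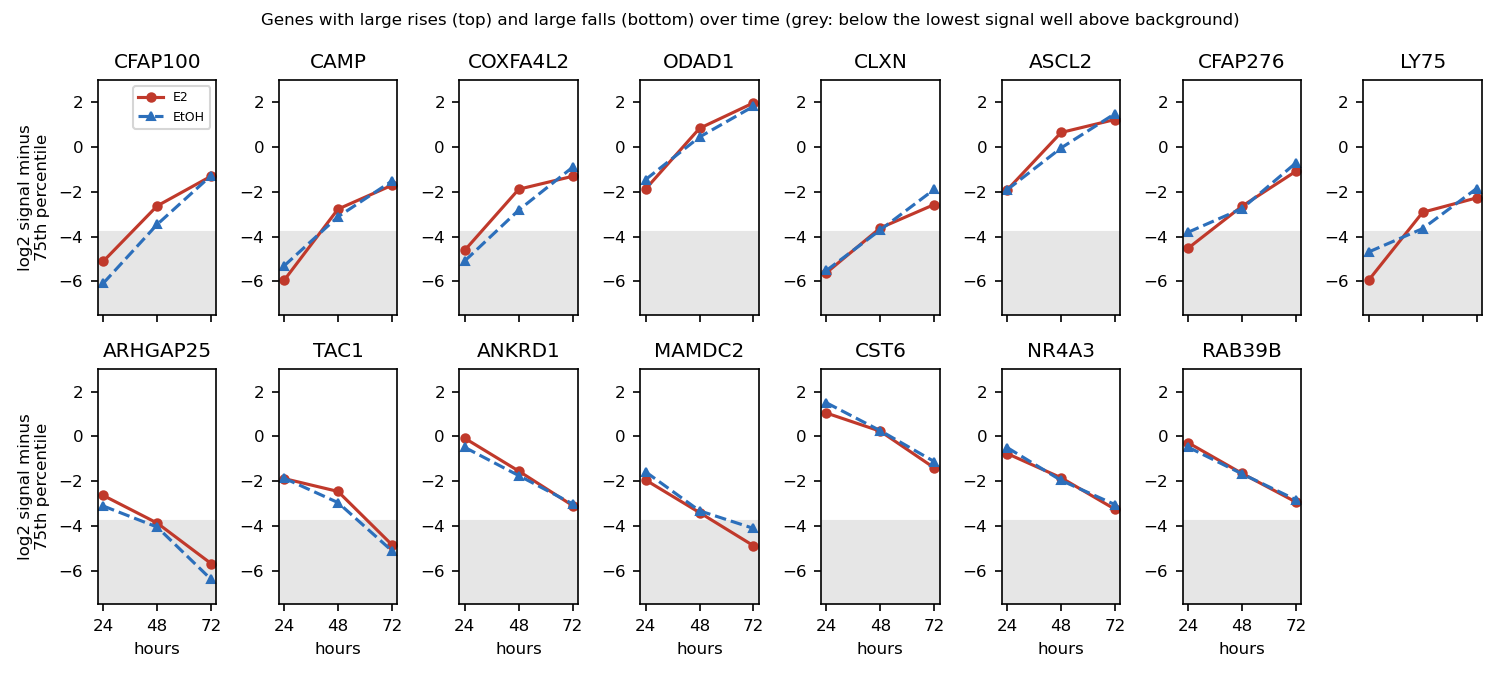
Levels (log2 signal minus the array's 75th percentile) of 8 genes with a large rise (top) and 7 with a large fall (bottom) against hours, 1 point per array, with E2 in red and EtOH in blue. Values in the grey band lie below the lowest signal well above background; the slope of ODAD1 was 1.78 and that of ANKRD1 −1.38 per 24 h.

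Of 26 endoplasmic reticulum stress genes 8 fell over all genes tested, and 17 fell and 1 rose adjusted over the list alone (median slope −0.36, camera adjusted p 1.2e-09). Their call was lost with adjusted p = 0.545 with an estimated correlation. DNAJB9, an endoplasmic reticulum chaperone partner, fell by 0.99 per 24 h (SE 0.12), the pseudokinase gene TRIB3 by 0.84 (SE 0.08) and HERPUD1, a component of protein disposal from the endoplasmic reticulum, by 0.65 (SE 0.08). Of 26 interferon-response genes 3 rose over all genes tested and 5 adjusted over the list alone (median 0.15, camera adjusted p 0.00129, and adjusted p = 0.545 with an estimated correlation). These were IFITM1 at 0.75 (SE 0.08), BST2, which tethers virus particles, at 0.73 (SE 0.09), and IFI44 at 0.58 (SE 0.10). Of 20 NF-κB targets and cytokines, TNF fell by 0.53 (SE 0.09) and IL11 by 0.45 (SE 0.08), and 6 fell and 1 rose adjusted over the list alone (median −0.18, camera adjusted p 0.00251, and adjusted p = 0.545 with an estimated correlation). Of 23 ribosome biogenesis genes 1 fell over all genes tested and 1 adjusted over the list alone, RRP12 by 0.52 (SE 0.09), with a list median of −0.14 (camera adjusted p 5.9e-04, and adjusted p = 0.545 with an estimated correlation). Of 30 ribosomal protein genes 0 passed limma over all genes tested and 0 adjusted over the list alone (median −0.12, camera adjusted p 0.0128, and adjusted p = 0.829 with an estimated correlation). Of 14 heat shock genes 1 fell over all genes tested and 2 adjusted over the list alone, HMOX1, heme oxygenase, falling by 0.80 (SE 0.11), with a list median of −0.24 (camera adjusted p 0.0453, and adjusted p = 0.829 with an estimated correlation). By fry, which asks whether a list's genes move on balance one way, the stress and the NF-κB lists also passed (adjusted p 0.0310 and 0.0404). These 6 medians kept their sign under all 5 scalings, but the ribosomal protein and heat shock lists passed camera under 3 of the 5 each.

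In all, 727 of 22183 genes passed limma for a slope over time, 510 rising and 217 falling, with 4639 at an unadjusted p under 0.05. The slope rests on 3 times, and the fit took the 2 arrays of a time as independent. Over the 18022 genes above background on all 8 arrays, E2 and EtOH arrays of the same time correlated at 0.994, 0.997 and 0.994 at 24, 48 and 72 h. A deviation shared by both arrays of a time would make these p-values too small. Time took up 74.8% of the sum of squares over genes on the 6 treated arrays, treatment 8.96% and the rest 16.2%. In simulated data the fit recovered 66% of genes changed by 2 over 48 h on the log2 scale and 0% of those changed by 1. The count rested on the first and last times: it was 0 without the E2 array at 24 h, 3 without E2 at 72 h, and 0 without EtOH at 24 h or at 72 h, against 1042 without E2 at 48 h and 420 without EtOH at 48 h. A direct comparison of 72 with 24 h, with 1 residual degree of freedom, called 4424, and the fit without a filter on dim probes 21.

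Treated cells differed from untreated Ishikawa cells in transfection, time, possibly medium and, in 1 arm, E2, and each arm was compared with the same single untreated array. The EtOH arrays also lay in another slide row than the untreated array, while the E2 arrays lay in the same row. OXT, which encodes the neuropeptide oxytocin, was 17.3-fold higher with E2 (difference 4.12, SE 0.27, limma adjusted p 0.0217) and 15.1-fold higher with EtOH (3.92, SE 0.27, adjusted p 0.0305), above untreated on 6 of 6 treated arrays. PGR was not above background in untreated cells and was at least 10.7-fold higher with E2 (limma adjusted p 0.232) and at least 9.43-fold higher with EtOH (adjusted p 0.312), which did not pass. These bounds hold for the values used here: with normexp and quantile normalisation the fitted log2 differences of 1.57 and 1.45 lay below them. Of 16 alternatives 2 passed in each arm. GREB1 was 3.43-fold and 3.35-fold above untreated (1.78 and 1.74, SE 0.59), ALPG 8.43-fold and 7.43-fold (3.08 and 2.89, SE 0.92) and EGR3 6.81-fold and 5.43-fold (2.77 and 2.44, SE 0.75), none of them passing. SERPINA1, alpha-1 antitrypsin, stood at 2.16 and 2.23 (SE 0.48), the transcription factor gene KLF4 at −0.96 and −1.11 (SE 0.24), and CYP1A1, a target of the aryl hydrocarbon receptor, at −0.99 and −0.95 (SE 0.36), also without passing. OXT was the only call among 22512 genes in each comparison, with 950 and 753 genes at an unadjusted p under 0.05 (limma, 1126 by chance). The call in both arms is not 2 separate findings, because the arms share the untreated array. In 50 simulations of unchanged arms sharing that array, the differences of the 2 arms had a mean r of 0.75 across genes. Those simulations gave 0.02 and 0.04 calls per arm and 0 in both on average, too few to judge an overlap. For independent lists 4.4e-05 would be expected in both. Simulated changes of 1 and 2 were recovered for 0% of genes in either comparison.

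Among 38 classical estrogen targets 4 rose in each arm adjusted over the list alone, and 0 over all genes tested by limma. The list's median was 0.07 with E2 and 0.06 with EtOH (camera adjusted p 0.0274 and 0.0118), which turned to −0.18 and −0.15 under median scaling, a scaling that shifted the median of all genes by −0.25 and −0.21, while the direction camera gave stayed up. These calls were lost with an adjusted p = 0.301 with an estimated correlation for E2 and adjusted p = 0.372 for EtOH. The 25 endometrial estrogen targets had a median of 0.31 with E2 and 0.11 with EtOH (camera adjusted p 0.0383 and 0.0582). With an estimated correlation their adjusted p was 0.301 and 0.386, and the E2 call held under 2 of 5 scalings. Set directly against each other, the 2 arms gave this list a median of 0.03 (camera adjusted p 0.632). Genes that estrogen lowers elsewhere had a median of −0.51 with E2 and −0.28 with EtOH (22 genes, camera adjusted p 6.9e-05 and 2.8e-05, and adjusted p = 0.301 and 0.372 with an estimated correlation). Mitosis genes had a median of −0.38 and −0.28, with 0 of 29 above 0 in either arm (adjusted p 1.9e-07 and 1.3e-05, and adjusted p = 0.353 and 0.440 with an estimated correlation). NF-κB targets and cytokines had a median of −0.51 and −0.35 (21 genes, adjusted p 0.00111 and 6.1e-05, and adjusted p = 0.439 and 0.386 with an estimated correlation), and the stress list −0.32 and −0.34 (26 genes, adjusted p 2.6e-04 and 2.8e-05, and adjusted p = 0.498 and 0.440 with an estimated correlation). In all, 14 lists passed for E2 and 10 for EtOH with the preset correlation, and 0 with an estimated one. The OXT call was kept in the E2 arm without E2 at 72 h, and lost without any other treated array; the EtOH call was lost without E2 at 24 or 48 h or any EtOH array and under median scaling. Setting only the 24 h array against the untreated one, 1 against 1 with the spread borrowed from the time-matched fit of the 6 treated arrays, called 61 genes for E2 and 47 for EtOH, and leaving the filter on dim probes out called 159 and 164.

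HEC-50B was set against untreated Ishikawa, 1 array each, so no difference has a replicate check and no test was run. VIM, the mesenchymal filament vimentin, was 6742-fold higher in HEC-50B, the collagen-binding glycoprotein gene SPARC at least 428-fold, the repressor of epithelial genes ZEB1 at least 74.2-fold and the receptor kinase AXL 96.0-fold. The epithelial keratin KRT19 was at least 3743-fold lower and CDH1, E-cadherin, at least 240-fold. Of 24 epithelial genes 15 were at least 4-fold lower and 0 higher, with a median of −3.41 at percentile 0 of 10000 random lists matched on level. Of 21 mesenchymal genes 12 were at least 4-fold higher and 0 lower, with a median of 2.53 at percentile 100. Among 27 NF-κB targets and cytokines 12 were at least 4-fold higher and 3 lower (median 1.55, percentile 100), the anti-apoptotic BIRC3 27.4-fold and IL11 26.0-fold higher, and PTGS2 at least 4.58-fold lower. Among 25 sterol synthesis genes 6 were at least 4-fold lower and 0 higher (median −1.49, percentile 0), HMGCS1 19.2-fold and CYP51A1 5.31-fold. An extreme percentile was also reached by lists without a gene 4-fold apart. Ribosome biogenesis stood at percentile 100 with 0 of 23 such genes, and DNA replication at 99.94 with 0 of 32. Respiratory chain and ATP synthase subunits, with 0 of 28, stood at 35.91. Random lists do not carry the co-expression of a list's genes, so these percentiles are a description and not a test. Other large differences were NNMT at least 4202-fold and FXYD2 2401-fold higher, and GSTP1, a detoxifying transferase, at least 10196-fold and the transcription factor gene SOX17 at least 968-fold lower. FXYD2 stood at −4.38 in untreated Ishikawa, just above that array's signal floor of −4.50, so the size of its fold is uncertain. PGR read 7.77 in HEC-50B on probe A_23_P138938 but was not above background on A_32_P49199 (−5.83), so its level there is unsettled. In all 4953 of 24519 genes were at least 4-fold apart, 2425 higher and 2528 lower in HEC-50B, and 2388 and 2311 of these also lay outside the range of the 7 Ishikawa arrays. Normexp background correction with quantile normalisation gave 1540, and a threshold of 8-fold gave 2949.

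**Figure D5:**
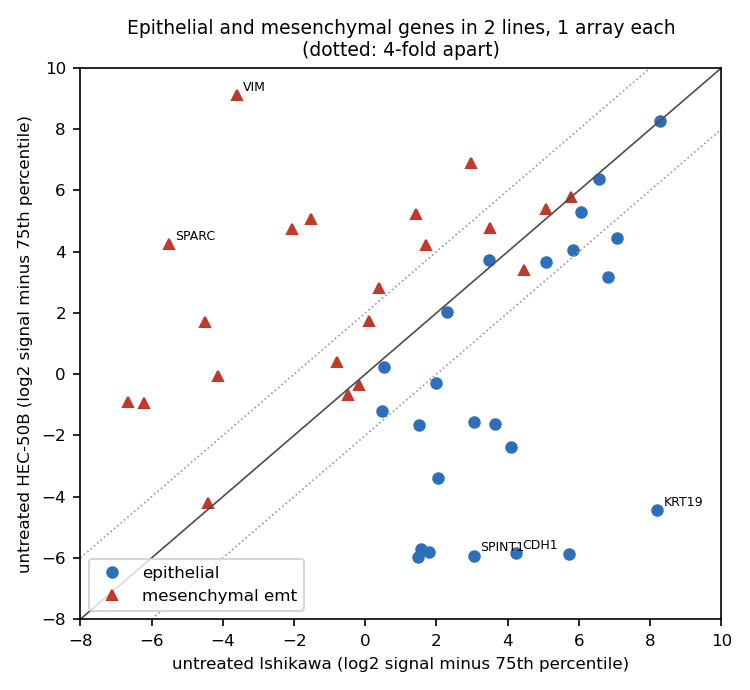
Levels (log2 signal minus the array's 75th percentile) of epithelial (blue) and mesenchymal (red) genes in untreated HEC-50B against untreated Ishikawa, 1 point per gene and 1 array per line; dotted lines mark 4-fold. VIM lies 6742-fold above the diagonal and CDH1 at least 240-fold below it.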

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

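The scaling to the 75th percentile over probes detected on all arrays, the fits with a common time slope in each arm against untreated cells, and all list alternatives except those for E2 against EtOH were chosen after seeing the data. All 8 arrays lay on 1 slide, so the slide could not be used as a block, and this alternative has no value. Matching arrays by time is the pairing here: without the time factor, that is with no replicate block, E2 against EtOH called 0 genes and 5 lists in place of 4, and it changed no other call. Scaling to the median shifted the median of all genes by −0.25 for E2 and −0.21 for EtOH against untreated cells and by −0.12 for the change of the E2 effect with time, and scaling on probes detected on all arrays shifted E2 against untreated by 0.12. No other scaling shift exceeded 0.1 in any fitted comparison. An array's median spot lay near the background limit, so median scaling rests on dim spots. Signal over background limits dim probes: genes not above background in a group are given as bounds, and 21 genes were called over time without a filter on dim probes.

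For E2 against EtOH the count was 0 under every alternative run except 8 under median scaling, and 0 to 91 with 1 pair left out. The 91 came without the 48 h pair, and each fit without a pair had 1 residual degree of freedom. For the change of the E2 effect with time it was 0 under every alternative run except with 1 array left out, which gave 0 to 151. For the time trend, 727 became 4424 for 72 against 24 h (1 residual degree of freedom), 21 with no filter, and 0 to 1042 with 1 array left out. The other settings gave 525 to 938. For E2 against untreated the 1 call became 2 with probes above background on every array, 2 with a trend in the prior, 2 with the deposited table, 159 with no filter, 61 with only the 24 h array (1 against 1, with the spread of the time-matched fit) and 93 with a common time slope, and 0 to 1 with 1 array left out. For EtOH against untreated it became 0 under median scaling, 2 above background on every array, 2 with a trend, 3 with the deposited table, 2 with the 75th percentile over probes detected on all arrays, 164 with no filter, 47 with only the 24 h array and 73 with a common time slope, and 0 to 3 with 1 array left out. For lists of E2 against EtOH, 4 became 0 with an estimated correlation, 0 with fry, 2 with quantile normalisation and 1 to 7 with 1 pair left out. For the time trend 6 became 0 with an estimated correlation and 2 with fry, and 6 to 9 with 1 array left out. For lists of E2 against untreated 14 became 0 with an estimated correlation, 0 with fry and 12 to 15 with 1 array left out; for EtOH 10 became 0, 0 and 9 to 11 in turn, and 6 with quantile normalisation. HEC-50B against Ishikawa gave 1540 with normexp and 2949 at 8-fold, in place of 4953. ESR1 minus untreated was −2.23, against 0.23 on probe A_23_P309739, −0.77 on A_24_P383478 and −2.44 to −1.99 with 1 array left out. The cause was not tested for these, except that an 8-fold threshold counts fewer genes by construction. Among named genes 301 values held, 128 were weaker, 5 stronger and 0 reversed.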

Other observations

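The tests of a hidden rise at estrogen-list genes, of estrogen activity in the ethanol arm, and the 3 tests on PGR and OXT were chosen only after the result was seen. Among the large rises, 10 genes read as motile-cilium genes had been noticed and were left out, whether or not they belonged to the families tested. Of 62 other tested genes from 12 motile-cilium families, 14 rose from 24 to 72 h, 0 fell and 51 had a slope above 0. TEKT2, a protein of ciliary microtubules, rose by 1.14 per 24 h (SE 0.08) and CFAP45, a protein inside those microtubules, by 1.06 (SE 0.08). Their E2 minus EtOH median was −0.01. Among immediate early genes FOS rose by 1.12 per 24 h (SE 0.10), FOSB by 1.06 (SE 0.11) and EGR2 by 0.92 (SE 0.15), while ATF3 fell by 0.84, with 1 of 3 other probes opposite; 5 of 24 rose and 1 fell over all genes tested, and 7 and 2 adjusted over the list alone (camera adjusted p 0.161).

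The count of 0 genes between E2 and EtOH was weighed first. The 10 splits of the 6 treated arrays are too few for a share under 0.05. The real split called 0 genes, as did the others (highest other 0, 10 of 10 as large). In the real split 1502 genes had an unadjusted limma p under 0.05. With time as a factor, a split that keeps both arrays of a time together compares E2 with EtOH only at the time it divides. Such splits repeat the treatment difference at 1 time, and they come in pairs with the same fit. They are thus not regroupings free of treatment, and the splits cannot tell whether the count of 0 is particular to the real labels. An exchange of labels at 1 time was argued against as the reason for the count only where many genes respond to E2. Turning the labels of 24, 48 or 72 h also called 0 genes (1395, 745 and 505 at an unadjusted p under 0.05). This does not settle whether labels were exchanged: across genes, which are not independent, the 24 h difference had r −0.19 with that at 48 h and 0.09 with that at 72 h, against 0.19 between 48 and 72 h. Leaving out the 48 h pair called 91 genes, with 1 residual degree of freedom. A hidden rise of 2-fold or more at most estrogen-list genes was argued against too, with 58 of 60 upper bounds below 1, and 53 of the 54 for genes above background on all 6 arrays. Estrogen-target expression already raised in the ethanol arm may remain, but its adjusted p with an estimated correlation was 0.372, so it stays open, and the slide row cannot be told apart from treatment.

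The time trend was weighed against the position of arrays on the slide, which would have made E2 minus EtOH equal to 1 slope at each time; the largest of the 3 coefficients was 0.018 (mean 0.0085, SD 0.010). Scaling as the cause was argued against as well, since 460 of 727 genes were called in the same direction under median scaling and 686 under quantile normalisation. As a hypothesis, motile-cilium genes may rise as a family: 22.6% of those not noticed rose against 2.66% of 13285 other named coding genes (odds ratio 10.7, Fisher's exact p 9.69e-10). Camera gave p 3.1e-12, and p = 0.0405 with an estimated correlation. The families were tested because large rises of such genes had been seen on these same arrays, so this is not an independent test. Fisher's test also takes genes as independent, and its p does not measure the spread between arrays. Time in culture, growth to confluence and time since transfection were not separated by the design.

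PGR and OXT were higher in both treated arms than in untreated cells, while no ESR1 probe was higher by as much. A failed untreated array was argued against only for the 18022 genes above background on all 8 arrays. Over these, its highest correlation with a treated array was 0.993, above the highest between treated arrays of different times, 0.991. Its lowest was 0.969, against 0.973 among treated arrays. Genes below background on the untreated array, PGR among them, were left out beforehand, so a loss of their signal there would not show. Probes of ESR1 outside the transfected cDNA may hide the transfected gene, and the largest rise of a probe in the mean of the 6 transfected arrays was 0.23, with single arrays of that probe from −1.15 to 0.08 against −0.84 untreated, but probe positions were not used here, so this stays open. Transfection or the change of medium, rather than E2, may raise both genes: E2 minus EtOH was at most 0.0539 of the rise for PGR, with the untreated level set to its floor, and 0.0486 for OXT, and all 3 EtOH arrays lay above untreated for each. Transfection, medium and time cannot be separated with 1 untreated array.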
